A study of Homo sapiens with 12 samples.

How the data were processed

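Total RNA from LNCaP cells was hybridised to 12 Illumina bead arrays, 4 for each of GSK8814 at 20 µM, GSK8815 at 20 µM and 0.10% DMSO, all after 24 h, per the labels. Groups and replicate numbers were taken from the sample titles. The vehicle level of the compound samples is not given in the labels.

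The values analysed are the authors' processed log2 values, 1 per probe and array, in the deposited value table of 47313 probes. Per the submitters' processing notes the tool was lumi, without a version. The values run from 6.05 to 14.6, and the 12 arrays share almost the same distribution (largest difference between arrays at any rank 0.0121), as between-array quantile normalization leaves it. That the scale is log2 was read from the values. Whether a plain logarithm or a variance-stabilising transform was used, and whether background was subtracted, is not given in the sources used here. A fold below is 2 to the power of a difference on that scale. A deposited scanner table with non-normalized signals and detection p-values was used only for its probe annotation. Its 48 per-array columns carry 12 run codes that match no sample label, so they were not assigned to samples and not used. The plan made before the data were examined was to normalize those signals with neqc and to filter on their detection p-values. It could not be followed, and the deposited log2 values were used with the same test.

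Probes were named through the probe identifier of the manifest part of that table, since in 889 rows the left-hand target name differs from the manifest gene. Of 47313 probes 37943 had a manifest row and 34673 a gene symbol. Symbols were updated with a RefSeq gene table of assembly GRCh38.p14 through the Entrez Gene identifier for 26575 probes and through an accession for 61, and 8037 kept the symbol of the file. Only 15 manifest rows carry a symbol that starts with A to E, so most genes of those letters, with ATAD2 and ATAD2B, are unnamed and not analysed here. No coordinates are given, because the build of the manifest is not given in the sources used here.

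The background level was taken from the values as the mode of all values (6.41) and its SD from the values below the mode (0.0918). A probe was kept if it exceeded the mode by 3 SD (6.69) on at least 4 of the 12 arrays, a filter chosen after seeing the data in place of the planned one. This kept 18519 probes, 13189 of them named. For each gene the named probe with the highest mean over the 12 arrays was used, which gave 10253 genes. Where several probes of a gene passed, a pair of them was taken, 2378 pairs in all. Among the pairs whose gene was called with GSK8814, 89.0% had the same sign of change with GSK8814. For shuffled pairs of these genes it was 45.7%. These genes were picked by the change of their brightest probe, and the share over all pairs was not computed.

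Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit of all 12 arrays, which share an estimate of the spread, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Intervals are 95% intervals of the same fit. Gene lists, 35 of them with 972 genes, were fixed before the data were examined. They were written from general knowledge of LNCaP cells, bromodomain inhibitors and common compound responses, so their names are not sourced descriptions of each member. Of their genes 684 have a named probe, and 28 lists with at least 5 measured genes were tested with camera (preset correlation 0.01), adjusted over the 28 lists of a comparison. Adjusted camera p-values with the correlation estimated from the data were computed beside these: 9 of 12, 10 of 13 and 7 of 10 list calls held in the comparisons of GSK8814 with DMSO, GSK8815 with DMSO and GSK8814 with GSK8815. For every list call the estimated correlation gave a larger p than the preset correlation, often by orders of magnitude. Beside each list the members past the test over all genes are counted, and those past it when adjusted over the list alone.

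Genes were named by a rule fixed before the data were examined: per comparison the 8 largest rises and the 8 largest falls among genes past the threshold whose groups do not overlap, the 3 members with the smallest p of the 6 lists with the smallest camera p, and fixed genes, among them ATAD2, ATAD2B, MYC and KLK3, where measured. Some genes this rule names are not reported here. If fewer than 5 genes of a direction passed, the smallest p would have filled the list. Values of these genes in the other comparisons may be given, and an undetected gene would be given only as such. Named after their values were seen were FKBP5, KLK4, EZH2, SGK1, SESN1, SQSTM1, FTL, GPNMB, HMGCS1, H4C3, UGT2B11, NQO1, MT1E, MT1F, MT2A, MT1X, TUBB3, VIM and VWF, and the members of lists too small to test.

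The steps were tested on simulated data with the real genes' means and spread, 10253 genes per comparison. Only a small part of the genes and a single list were seeded, and noise was drawn independently for each gene. The share called depends on how many genes change, so these shares need not hold for the real comparisons. Seeded changes of 0.2, 0.3, 0.5 and 1 on the log2 scale were called for 38%, 82%, 98% and 100% of the genes in the simulated GSK8814 against DMSO comparison, and 1.23% of the calls were not seeded. For GSK8815 against DMSO the shares were 32%, 72%, 100% and 100%, with 6.13% of calls not seeded, and for GSK8814 against GSK8815 28%, 80%, 98% and 100%, with 4.97%. The simulated comparisons differ only in the random draw, so differences between their shares are noise of that draw. The seeded list passed in each of them. Of the other lists 1 passed in the simulated GSK8814 against DMSO comparison and 0 in the others.

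Alternatives were no filter, a stricter filter (mode plus 5 SD on all 12 arrays), every probe tested, the mean of the probes of a gene, only the groups compared, a replicate block, array weights, a variance trend with robust estimation, a minimum of 1.5-fold, fry, cyclic loess, background subtraction, and each array left out in turn. The stricter filter, cyclic loess and background subtraction (log2 of the linear value minus the background mode plus an offset) were chosen after seeing the data and the first results. Ranges of list p-values over alternatives leave out fry, which tests a list against no change. The test on single members of the BET inhibitor list (HEXIM1, SERPINI1 and ZCCHC24) was written before their values were seen but after the totals of that list were. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and figures.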

Results

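Gene expression was measured on 12 Illumina bead arrays of total RNA from LNCaP, an established human prostate cancer cell line that responds to androgen. The cells had been kept for 24 h with GSK8814 at 20 µM, with GSK8815 at 20 µM or with 0.10% DMSO, the vehicle, and each group held 4 arrays. The series presents GSK8814 as a chemical probe for the bromodomain of ATAD2, a chromatin-bound ATPase. GSK8815 was tested beside it as a companion compound. The design gives 3 comparisons, each compound against DMSO and the 2 compounds against each other at a matched dose and time. Array medians lay between 6.539 and 6.541 on the log2 scale, and between 17822 and 17847 probes per array were above background. Such likeness follows from the nearly identical distributions of the deposited values and does not measure array quality. The number of arrays limits the precision: the median standard error of a log2 difference was 0.0614. The labels do not say whether the 4 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The probes of ATAD2 and ATAD2B could not be named and were not analysed here.

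The comparison of GSK8814 with DMSO asks what the ATAD2 probe does to transcription in these cells. GSK8814 lowered genes of mitosis and DNA replication together and raised genes of cholesterol and fatty acid synthesis, of the histone family, of the NRF2 response and of the lysosome. The named gene with the largest fall was TM4SF1, a cell surface protein of the transmembrane 4 family, which went from 11.5 ± 0.0916 (SD, n = 4) in DMSO to 10.1 ± 0.0779 (SD, n = 4), 2.62-fold lower. FOXN4, a forkhead transcription factor, showed the largest rise among named genes, from 7.22 ± 0.0360 (SD, n = 4) to 8.52 ± 0.0554 (SD, n = 4), 2.46-fold higher. Of 10253 named genes tested with limma, 2463 passed a Benjamini-Hochberg adjusted p of 0.05, of which 1299 were higher and 1164 lower. Most changes were small: the median fold among these genes was 1.19, 153 reached 1.5-fold (40 higher and 113 lower) and 9 reached 2-fold. Genes named below outside the rule for naming genes were chosen after their values were seen.

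The mitosis list, fixed in advance, moved as a block. All 28 of its measured members fell with GSK8814, also adjusted over the list alone, with a median log2 change of -0.79 (camera adjusted p = 1.08e-49, adjusted p = 5.04e-06 with an estimated correlation). NUSAP1, which binds spindle microtubules, fell by 1.11 on the log2 scale (SE 0.0556, limma adjusted p = 1.37e-14). KIF20A, a kinesin of cytokinesis, fell by 1.05 (SE 0.0640). UBE2C, a ubiquitin-conjugating enzyme that works with the anaphase-promoting complex, fell by 0.95 (SE 0.0584), with its 3 probes between -1.07 and -0.33. TOP2A, the topoisomerase of dividing cells, went from 10.4 ± 0.138 to 9.35 ± 0.0605 (SD, n = 4 each). The spindle protein gene FAM83D and the mitotic regulator gene PIMREG, outside that list, were 2.14-fold and 2.01-fold lower. Of 34 measured genes of DNA replication and E2F control, 32 fell, and 34 when adjusted over the list alone. Their median was -0.65 (camera adjusted p = 5.80e-41, adjusted p = 2.06e-05 with an estimated correlation). GINS2 and MCM4, 2 parts of the replicative helicase, fell by 0.95 (SE 0.0657) and 0.87 (SE 0.0582), and MCM5 of the same complex fell by 0.85 (SE 0.0609). Genes of ribosome biogenesis and other MYC targets fell less. In that list 16 of 37 members were lower and 1 was higher, or 21 and 1 adjusted over the list alone. The median was -0.15 (camera adjusted p = 1.52e-07, adjusted p = 0.00419 with an estimated correlation). LYAR and NOLC1, 2 nucleolar proteins, fell by 0.53 (SE 0.0583) and 0.41 (SE 0.0600). PUS1, a pseudouridine synthase, fell by 0.39 (SE 0.0607) on its brightest probe, while 1 of its 3 probes was at 0.04 and their mean at -0.24. MYC itself differed by 0.04 (SE 0.0639, adjusted p = 0.740), with a 95% interval from -0.09 to 0.17, and was at -0.0048 without DMSO replicate 2.

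Sterol genes moved the other way. In the cholesterol list 14 of 18 measured members rose and 1 fell, or 15 and 1 adjusted over the list alone. The median was 0.40 (camera adjusted p = 3.31e-12, adjusted p = 0.00137 with an estimated correlation). TM7SF2, a sterol C14 reductase, rose 1.89-fold (log2 0.92, SE 0.0596). LSS, which closes the sterol ring, rose 1.78-fold (log2 0.83, SE 0.0633), and INSIG1, a sterol-dependent brake on SREBP processing, rose 1.61-fold (log2 0.69, SE 0.0559). HMGCS1, early in the pathway, rose 1.55-fold. In the fatty acid synthesis list 9 of 11 measured members rose, also adjusted over the list alone. The median was 0.31 (camera adjusted p = 1.41e-07, adjusted p = 0.00137 with an estimated correlation). Among those that rose were LPIN1 by 0.66 (SE 0.0617), the desaturase gene SCD by 0.56 (SE 0.0553) and malic enzyme ME1 by 0.50 (SE 0.0551).

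Histone genes moved both ways. Of 30 measured members, 18 rose and 5 fell, or 19 and 5 adjusted over the list alone. The median was 0.30 (camera adjusted p = 3.66e-06, adjusted p = 0.00384 with an estimated correlation). Divided after the values were seen, and without a test between the kinds, 17 of 24 replication-dependent genes rose and 1 fell, and 1 of 6 variant genes rose and 4 fell. H2BC21 rose 2.13-fold (log2 1.09, SE 0.0621) and H4C8 rose 1.65-fold (log2 0.72, SE 0.0597). H4C3 fell by 0.63 (SE 0.0621), as did the variant gene H2AX (SE 0.0686). Histone genes have near-identical copies, so a value of 1 member can hold signal of another. In the NRF2 list 9 of 21 members rose, 11 adjusted over the list alone (median 0.14, camera adjusted p = 5.52e-07, adjusted p = 0.00419 with an estimated correlation). SQSTM1, an autophagy receptor, was up 1.65-fold and ferritin light chain FTL up 1.48-fold. In the lysosome list 14 of 25 members rose and 3 fell, 15 and 3 adjusted over the list alone. The median was 0.18 (camera adjusted p = 4.95e-06, adjusted p = 0.00743 with an estimated correlation). GPNMB, a lysosomal and melanosomal membrane glycoprotein, rose by 0.68 (SE 0.0565). Other large rises were in ST3GAL1, a sialyltransferase (1.97-fold), GDF15, a stress-responsive cytokine (1.97-fold), TP53INP1, a p53-inducible gene (1.87-fold), the phosphatase gene PTPRR (1.86-fold) and the potassium channel gene KCNG1 (1.84-fold). The 2 probes of PTPRR differed in size, at 0.90 and 0.10, and their mean was 0.50. Probes also differed for ST3GAL1 (0.98 and 0.34) and for INSIG1 (0.69 and 0.34). The mean of the LSS probes was 0.51.

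Of 16 genes listed from general knowledge as depending on ATAD2, 10 were measured and 7 fell, 8 adjusted over the list alone. The median was -0.42 (camera adjusted p = 1.28e-07, adjusted p = 0.00137 with an estimated correlation). The list shares 4 of those 10 genes, all kinesins, with the mitosis list. KIF20A, KIF15 (-0.57, SE 0.0599) and KIF4A (-0.52, SE 0.0581) had the smallest p. Of the 6 other members 3 fell: EZH2, a histone methyltransferase, by 0.44, KLK3, which encodes prostate-specific antigen, by 0.39 (SE 0.0591, adjusted p = 7.56e-06), and the kinase gene SGK1 by 0.32. With the probes of a gene averaged, KLK3 was at -0.23 and SGK1 at -0.21, and after background subtraction SGK1 was at -0.66. The androgen-induced list did not pass (camera adjusted p = 0.210): 5 of its 28 measured members were higher and 8 lower, 5 and 10 adjusted over the list alone. FKBP5 and KLK4, both induced by androgen in these cells, went opposite ways, by -0.52 (SE 0.0570) and 0.56 (SE 0.0952). UGT2B28, a steroid glucuronosyltransferase gene, was 2.35-fold lower.

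The lists of BET-inhibitor-raised genes, LXR targets and p53 targets passed only with the preset correlation. The BET list had 4 of 10 members higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0245, adjusted p = 0.0663 with an estimated correlation, in a range of 0.0009285 to 0.0663 over its camera alternatives), and 3 of the 4 were histone genes. Of 5 LXR targets 3 rose, also adjusted over the list alone (camera adjusted p = 0.0245, adjusted p = 0.0753 with an estimated correlation, and 0.0575 without DMSO replicate 1, with a range of 0.000647 to 0.0753 over its camera alternatives). Of 22 p53 targets 6 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.04997, adjusted p = 0.110 with an estimated correlation). The p53 call ended without DMSO replicate 1 (0.0686) or 3 (0.0521), without GSK8814 replicate 1 (0.0799) or 4 (0.0674), and after background subtraction (0.139), with a range of 0.00492 to 0.139 over its camera alternatives. Few markers of other cell types were measured. VIM, a mesenchymal marker, was at 0.20 (adjusted p = 0.0215) and VWF, an endothelial marker, at -0.18 (adjusted p = 0.0284). The VIM call ended without DMSO replicate 1 (adjusted p = 0.0874), without GSK8814 replicate 1 (0.0939) and after background subtraction (0.0619), with a range of 0.0120 to 0.0939 over its alternatives. The VWF call ended without DMSO replicate 1 (0.0663) or 3 (0.114) or GSK8814 replicate 4 (0.103), with a range of 0.0153 to 0.114, and background subtraction moved VWF to -0.29. TUBB3, a neuronal tubulin, rose 1.34-fold.

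All 4 GSK8814 arrays lay on 1 side of all 4 DMSO arrays for 23.2% of the genes, where chance gives 2.86%. Fold changes are on the deposited scale, and whether background was subtracted there is not given in the sources used here, so changes of dim genes may be understated. Subtracting a background estimated from the values moved KIF15 from -0.57 to -0.92 and KIF4A from -0.52 to -0.82.

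**Figure D1:**
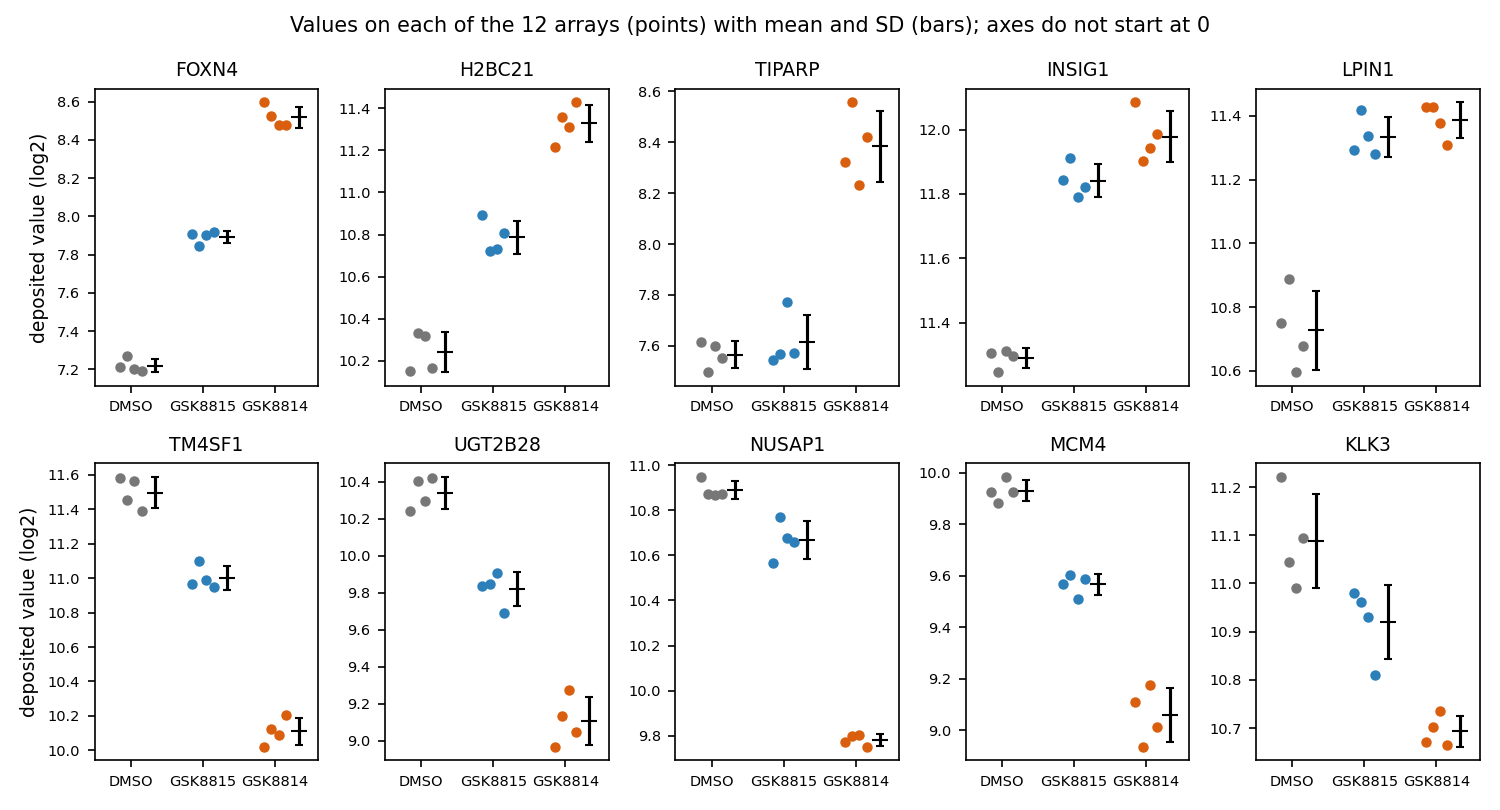
Deposited log2 values (vertical axes, which do not start at 0) of 10 genes on each of the 12 arrays, by group, with the mean and SD of the 4 arrays as a bar. For FOXN4 the GSK8815 mean (7.89) lies between those of DMSO (7.22) and GSK8814 (8.52), for LPIN1 both compounds lie close together (11.3 and 11.4), and for TIPARP GSK8815 (7.61) lies near DMSO (7.57).

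The comparison of GSK8815 with DMSO gives the response to the companion compound. GSK8815 raised genes of lipid synthesis and metallothioneins and lowered the same mitosis and replication lists as GSK8814, by less. FOXN4 was among the 8 largest rises of named genes, from 7.22 ± 0.0360 (SD, n = 4) to 7.89 ± 0.0324 (SD, n = 4), 1.59-fold higher. The largest fall among named genes was in UGT2B28, from 10.3 ± 0.0862 (SD, n = 4) to 9.82 ± 0.0918 (SD, n = 4), 1.44-fold lower. With limma 675 of 10253 genes passed, 345 higher and 330 lower, and 7 of them reached 1.5-fold, all of these higher.

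In the cholesterol list 11 of 18 members rose, 13 adjusted over the list alone. The median was 0.27 (camera adjusted p = 9.71e-18, adjusted p = 0.000478 with an estimated correlation). INSIG1 rose by 0.55 (SE 0.0559, adjusted p = 2.34e-07, other probe at 0.26), LSS by 0.52 (SE 0.0633, or 0.33 with its probes averaged), and HMGCS1 by 0.40. MSMO1, a sterol C4 methyl oxidase, rose by 0.63 (SE 0.0667), although 1 of its 3 probes was at -0.06 and their mean at 0.30. In the fatty acid synthesis list 6 of 11 members rose, 7 adjusted over the list alone. The median was 0.28 (camera adjusted p = 2.85e-10, adjusted p = 0.000478 with an estimated correlation). LPIN1 was at 0.61 (SE 0.0617), SCD at 0.40 (SE 0.0553) and the desaturase gene FADS1 at 0.37 (SE 0.0579). Of 8 metallothionein list members 5 rose, 6 adjusted over the list alone. The median was 0.22 (camera adjusted p = 5.66e-06, adjusted p = 0.00334 with an estimated correlation). MT1H was at 0.46 (SE 0.0647), MT1G at 0.41 (SE 0.0672) and MT1A at 0.24 (SE 0.0622). The MT1A call ended without GSK8815 replicate 2 (adjusted p = 0.0559) or 4 (0.0639) and after background subtraction (0.0770), with a range of 0.0109 to 0.0770 over its alternatives. The lysosome list (6 of 25 higher and 1 lower, 9 and 2 adjusted over the list alone), the NRF2 list (5 of 21 higher, 6 and 1 lower adjusted over the list alone) and the histone list (3 of 30 higher and 1 lower, 5 and 1 adjusted over the list alone) also rose. Their camera adjusted p were 7.46e-06, 0.000415 and 0.01003, and 0.00995, 0.0245 and 0.0466 with an estimated correlation. H2BC21 rose by 0.55 (SE 0.0621). Other genes with large rises were PTPRR (1.61-fold; log2 0.69, or 0.36 with its probes averaged), GDF15 (1.55-fold) and the hormone gene RLN2 (1.54-fold).

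Of 28 mitosis genes 16 fell with GSK8815, 25 adjusted over the list alone. The median was -0.22 (camera adjusted p = 7.90e-21, adjusted p = 0.00021 with an estimated correlation). KIF14 (-0.35, SE 0.0575), TACC3 (-0.30, SE 0.0561) and KIF2C (-0.34, SE 0.0642), all of the mitotic spindle, had the smallest p, and PIMREG was 1.37-fold lower. Of 34 replication genes 18 fell, 24 adjusted over the list alone, led by GINS3 (-0.42, SE 0.0630), MCM2 (-0.41, SE 0.0592) and MCM4 (-0.36, SE 0.0582). The list median was -0.21 (camera adjusted p = 2.17e-20, adjusted p = 0.000389 with an estimated correlation). In the MYC target list 10 of 37 fell, 13 adjusted over the list alone, with NOLC1 at -0.29, PA2G4 at -0.30 and WDR74 at -0.27. The list median was -0.12 (camera adjusted p = 1.81e-09, adjusted p = 0.00244 with an estimated correlation). The calls of PA2G4 and WDR74 ended after background subtraction (adjusted p = 0.0625 and 0.0631) and that of WDR74 without DMSO replicate 1 (0.0613). Over all alternatives their adjusted p ranged from 0.00506 to 0.0625 and from 0.00166 to 0.0631. WDR74 also had 1 of 3 probes on the other side of 0. Of 10 measured members of the list named for ATAD2 dependence 3 fell, 6 adjusted over the list alone. The median was -0.17 (camera adjusted p = 0.000510, adjusted p = 0.0120 with an estimated correlation). FKBP5 was lower by 0.37 on the log2 scale (adjusted p = 0.000146), while KLK3 was at -0.17 (adjusted p = 0.0892, and 0.0315 with its probes averaged, in a range of 0.0315 to 0.279 over its alternatives). MYC was at -0.01 (adjusted p = 0.944), and above 0 with its probes averaged (0.05), without DMSO replicate 1 (0.02) or 3 (0.0022) and without GSK8815 replicate 1 (0.03). TM4SF1 was 1.41-fold lower, the pseudokinase gene PRAG1 1.39-fold, pepsinogen gene PGC 1.37-fold and LOC652595, a symbol kept from the file, 1.33-fold.

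The calls of 3 more lists ended with an estimated correlation. Of 9 androgen-repressed genes 2 were higher, 3 adjusted over the list alone (camera adjusted p = 0.0382, adjusted p = 0.0829 with an estimated correlation). That call also ended without DMSO replicate 4 (0.0686), without GSK8815 replicate 1 (0.0501), 3 (0.0627) or 4 (0.0564), after background subtraction (0.0667) and with a stricter filter (0.0607), with a range of 0.00585 to 0.0829 over its camera alternatives. Of 5 LXR targets 1 was higher, 2 adjusted over the list alone (camera adjusted p = 0.02995, adjusted p = 0.0829 with an estimated correlation). It ended without DMSO replicate 1 (0.0712) and without GSK8815 replicate 1 (0.0501) or 3 (0.0513), with a range of 0.003055 to 0.0829 over its camera alternatives. Of 7 NF-kB targets 1 was lower, 2 adjusted over the list alone (camera adjusted p = 0.0382, adjusted p = 0.226 with an estimated correlation), and it ended without DMSO replicate 1 (0.0859) or 2 (0.0913), without GSK8815 replicate 2 (0.0829) or 4 (0.0752), and with no filter (0.343), with a range of 0.0127 to 0.343 over its camera alternatives.

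The 4 arrays of GSK8815 and of DMSO did not overlap for 12.2% of the genes, where chance gives 2.86%. The count of 675 fell to 445 without GSK8815 replicate 1 (231 higher and 214 lower) and to 381 after background subtraction, which also moved FOXN4 from 0.67 to 1.08, RLN2 from 0.62 to 0.998 and PGC from -0.46 to -0.69.

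**Figure D2:**
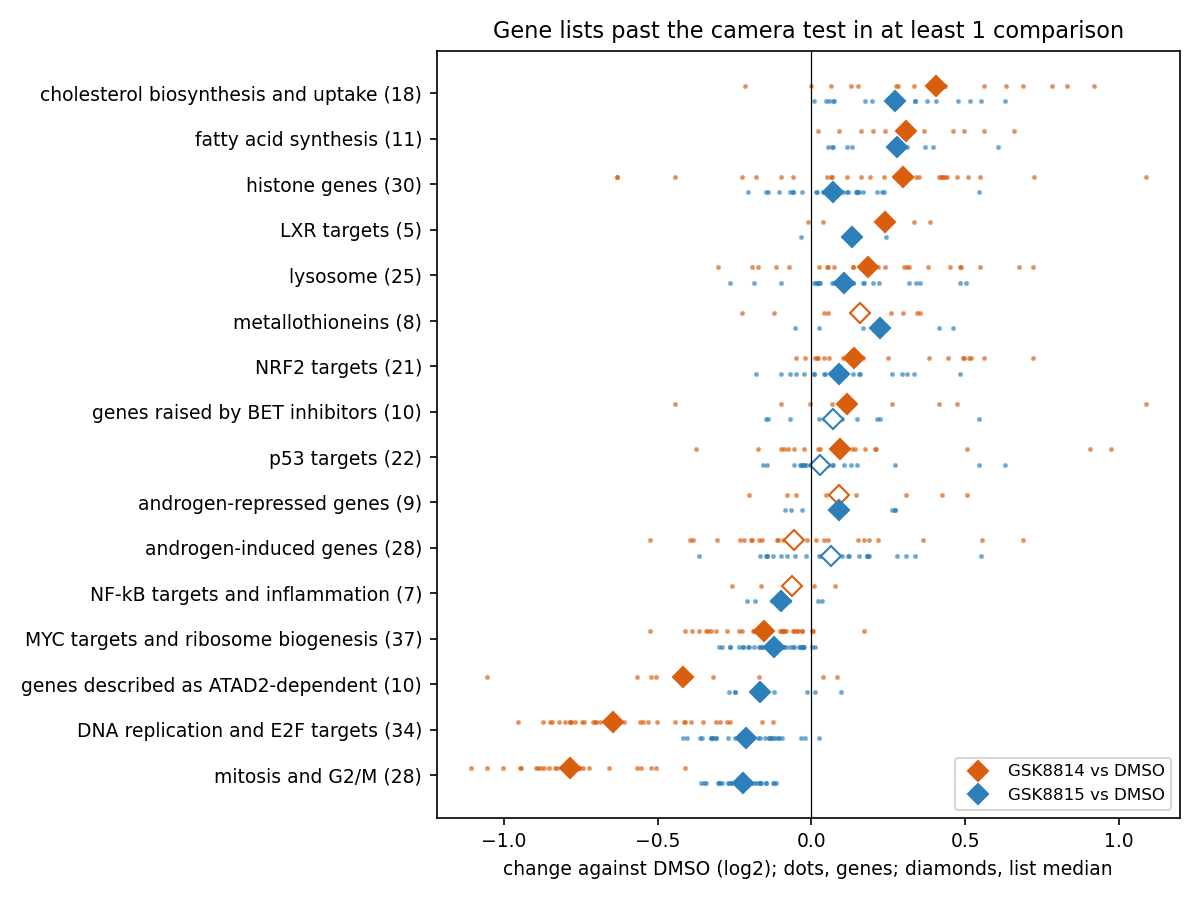
Log2 change against DMSO (horizontal axis) of the measured members (dots) and the median (diamonds) of the 16 gene lists that passed the camera test in at least 1 comparison. Orange is GSK8814, blue is GSK8815, a filled diamond marks a list that passed against DMSO, and the number measured stands in brackets. The medians of the mitosis list are -0.79 and -0.22 and those of the fatty acid list 0.31 and 0.28.

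The direct comparison of GSK8814 with GSK8815 asks which responses differ between the compounds at the same dose and time. GSK8814 gave lower levels of mitosis and replication genes than GSK8815 and higher levels of several histone and NRF2 genes. TIPARP, a poly-ADP-ribosyltransferase gene induced by the aryl hydrocarbon receptor, differed most among named genes higher with GSK8814, at 8.38 ± 0.138 (SD, n = 4) against 7.61 ± 0.107 (SD, n = 4), 1.70-fold higher. TM4SF1 differed most among named genes lower with GSK8814, at 10.1 ± 0.0779 against 11.002 ± 0.0686 (SD, n = 4 each), 1.86-fold lower. With limma 699 genes differed, 278 higher and 421 lower with GSK8814, and 32 of them by at least 1.5-fold (5 higher and 27 lower).

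All 28 mitosis genes were lower with GSK8814 than with GSK8815, also adjusted over the list alone. The median was -0.58 (camera adjusted p = 5.45e-69, adjusted p = 1.17e-06 with an estimated correlation). NUSAP1 was at -0.89 on the log2 scale (SE 0.0556), KIF20A at -0.79 (SE 0.0640) and UBE2C at -0.70 (SE 0.0584). FAM83D (1.76-fold), TOP2A (1.67-fold) and HMMR (1.63-fold), which act on the spindle or chromosomes, were among the 8 largest falls of named genes, as was UGT2B28 (1.64-fold). Of 34 replication genes 29 were lower, 33 adjusted over the list alone, led by POLA2 (-0.63, SE 0.0620), GINS2 (-0.63, SE 0.0657) and TYMS (-0.62, SE 0.0651). The list median was -0.40 (camera adjusted p = 3.32e-48, adjusted p = 1.02e-05 with an estimated correlation). Of 10 measured members of the list named for ATAD2 dependence 6 were lower, 7 adjusted over the list alone. The median was -0.21 (camera adjusted p = 3.20e-08, adjusted p = 0.00153 with an estimated correlation), with KIF15 and KIF4A both at -0.40 beside KIF20A. After background subtraction KIF15 was at -0.67 and KIF4A at -0.64. The MYC target list did not pass (median -0.03, camera adjusted p = 0.0661), and MYC differed by 0.05 (adjusted p = 0.749), or by -0.03 with its probes averaged.

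Of 30 histone genes 14 were higher with GSK8814 and 3 lower, 18 and 4 adjusted over the list alone. The median was 0.20 (camera adjusted p = 7.34e-07, adjusted p = 0.00319 with an estimated correlation). H4C8 was at 0.56 (SE 0.0597), H2BC21 at 0.54 (SE 0.0621) and H2AX at -0.57 (SE 0.0686). Of 21 NRF2 targets 8 were higher, 9 adjusted over the list alone, with OSGIN1 at 0.38 and ferritin heavy chain FTH1 at 0.35. The list median was 0.13 (camera adjusted p = 1.75e-06, adjusted p = 0.00812 with an estimated correlation). Of 28 androgen-induced genes 3 were lower with GSK8814, 7 lower and 1 higher adjusted over the list alone (median -0.09, camera adjusted p = 0.000176, adjusted p = 0.0366 with an estimated correlation). The 3 were PMEPA1 (-0.37, SE 0.0574), NDRG1 (-0.33, SE 0.0590) and KLK3 (-0.23, SE 0.0591). Averaging probes put PMEPA1 at -0.24. The KLK3 difference (adjusted p = 0.0144) did not pass without GSK8815 replicate 1 (0.0555) or 2 (0.0510), after background subtraction (0.0610) or with its 3 probes averaged (-0.07, adjusted p = 0.417), 1 of which was at 0.06. Over all alternatives its adjusted p ranged from 0.00810 to 0.417. ZIC2 (1.56-fold), FOXN4 (1.54-fold), KCNG1 (1.53-fold), the kinase gene NEK8 (log2 0.59, SE 0.0651) and IGFBP3 (1.45-fold) were also higher with GSK8814. NEK8 moved from 0.59 to 0.93 after background subtraction.

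Few lipid genes passed between the compounds. Of 18 cholesterol genes 3 were higher with GSK8814 and 1 lower, 8 and 1 adjusted over the list alone (median 0.12, camera adjusted p = 0.000431, adjusted p = 0.0491 with an estimated correlation). TM7SF2 and LSS were higher by 0.44 (SE 0.0596) and 0.32 (SE 0.0633), and LSS by 0.18 with its probes averaged (adjusted p = 0.0466, in a range of 0.000494 to 0.0466). For INSIG1 the difference was 0.14 (95% interval 0.02 to 0.25, adjusted p = 0.160) and for LPIN1 0.05 (-0.07 to 0.18), neither past the threshold. The fatty acid list (1 of 11 higher, 3 adjusted over the list alone), the lysosome list (5 of 25 higher, 9 and 1 lower adjusted over the list alone) and the BET list (3 of 10 higher and 1 lower, the same adjusted over the list alone) passed at camera adjusted p of 0.0389, 0.00180 and 0.0339, but with an estimated correlation their adjusted p were 0.0830, 0.0505 and 0.0813. The fatty acid call ended without GSK8814 replicate 2 (0.0739) or 3 (0.0626), without GSK8815 replicate 1 (0.0805) or 4 (0.0791) and after background subtraction (0.0608), with a range of 0.0119 to 0.0830 over its camera alternatives. The BET call ended without GSK8814 replicate 2 (0.0739) or 3 (0.0619), without GSK8815 replicate 2 (0.0716) or 4 (0.0505) and after background subtraction (0.0608), with a range of 0.00370 to 0.0813 over its camera alternatives, and the lysosome list ranged from 7.33e-05 to 0.0505 over the same alternatives. The metallothionein list did not pass (camera adjusted p = 0.0571).

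The groups did not overlap for 12.4% of the genes, against 2.86% by chance, and background subtraction lowered the number of genes higher with GSK8814 from 278 to 156.

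**Figure D3:**
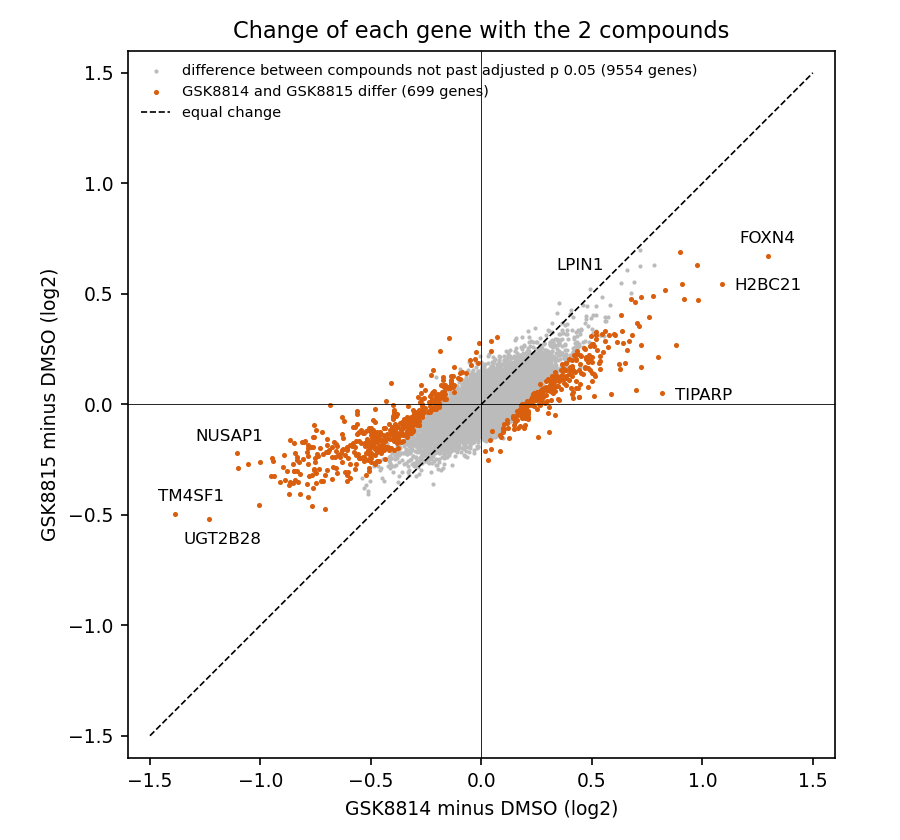
Log2 change with GSK8814 (horizontal axis) against that with GSK8815 (vertical axis), both relative to the same 4 DMSO arrays, for 10253 genes (points). Orange points are the 699 genes that differed between the compounds, and the dashed line marks equal change. LPIN1 lies near the line (0.66 and 0.61), FOXN4 (1.30 and 0.67) and TM4SF1 (-1.39 and -0.50) lie off it, and TIPARP lies near 0 for GSK8815 (0.05).

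The log2 changes of the 2 compounds against DMSO correlated across genes with Pearson's r = 0.783, where genes are not independent replicates. Both changes use the same 4 DMSO arrays, and simulated groups without any effect gave r = 0.5001. The covariance was 0.0154 against a simulated 0.00200, a difference of 0.0134. With the DMSO arrays split between the comparisons, the mean of the 6 splits was r = 0.582 with a covariance of 0.0130. Of the genes called with both compounds 309 were higher in both and 296 lower in both. Independent lists of the same sizes would share 43.7 and 37.5, a reckoning that leaves out the shared DMSO arrays. That sharing favours calls in the same direction. With limma 0 genes were called in opposite directions, and 5 were opposite at an unadjusted p under 0.05 in both. Of the shared calls 413 did not differ past the threshold between the compounds, and 70 genes were called with GSK8815 but not with GSK8814.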

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

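The tests of a single scale factor, of histone classes, of androgen response output and of UGT2B11 were chosen only after the results were seen. The test on members of the BET list was written after the totals of that list were seen but before the values of those members were. The other tests in this part were chosen before.

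Whether other groupings of the arrays give as many calls was examined by refitting the 35 splits of the 8 arrays of each comparison into 4 and 4, with the real split counted. For GSK8814 against DMSO only the real split, 1 of 35, gave as many genes: 2463 against at most 0 in the other 34 with limma, where up to 1200 had an unadjusted p under 0.05 against 3501 in the real split. For GSK8815 against DMSO it was 1 of 35 (675 against at most 4), and for GSK8814 against GSK8815 1 of 35 (699 against at most 2). The numbers of lists were 12 against at most 11, 13 against at most 11 and 10 against at most 9, again with 1 split of 35 reaching the real value. Chance spread between single arrays as the source of the 6 counts is thus argued against. Still, 1 of 35 is the smallest share these splits can give and the margin for the lists is narrow. In the other splits the real group difference enters the residual spread, which lowers their gene counts. If the arrays of a group share a culture, a difference between cultures would also set the real split apart, so the splits cannot speak to it. The high list counts came from splits that kept 3 of the 4 arrays of a group together and so still held part of the group difference. Splits that mixed the groups 2 and 2 passed at most 1 list.

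Over all genes 77.4% had the same sign of change with both compounds, against 66.6% in simulated groups without an effect, and the lists named below changed less with GSK8815. Noise of single DMSO arrays, used in both comparisons, is argued against as the source of the likeness. The lowest covariance with the DMSO arrays split between the comparisons was 0.0126, against 0.0154 unsplit. That explanation puts the lowest at 0 or below. A deviation common to all DMSO arrays, such as that of a shared culture, would stay in both parts of a split. The splits thus cannot speak to such a deviation. A single response scaled down by 1 factor is also argued against. The mean change of the list members with GSK8815 was 0.71 of that with GSK8814 in the cholesterol list and 0.29 in the mitosis list. The difference of these ratios was 0.425 (95% bootstrap interval over resampled arrays 0.363 to 0.483). The ratio was 0.75 in the fatty acid list, 0.75 in the MYC target list, 0.59 in the lysosome list, 0.36 in the replication list and 0.35 in the histone list. List medians would give other ratios. With GSK8814 and GSK8815 the medians were 0.31 and 0.28 in the fatty acid list and 0.30 and 0.07 in the histone list. It may be that parts of the response depend to different degrees on what sets GSK8814 apart, but saturation of some parts would look alike and was not tested, since 1 dose was used.

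Most replication-dependent histone genes, 17 of 24, rose with GSK8814 (1 fell) while replication genes fell, although such histone genes are made in S phase. Cross-hybridisation within a single class is argued against, because genes that rose came from 4 of the 5 classes (7 of 7 H2A, 5 of 9 H2B, 2 of 2 H3 and 3 of 5 H4 genes). Signal shared inside each class stays open. A response like that to BET inhibitors cannot be told apart from others here: of the members of that list that are not histone genes, 1 (SERPINI1, 0.26, and 0.52 after background subtraction) rose, while HEXIM1 was at -0.00 and ZCCHC24 at 0.12. Histone mRNAs of this kind mostly lack a poly(A) tail, and how the RNA was primed for labelling is not given in the sources used here, so a change in tailed histone transcripts is a candidate explanation that was not tested.

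The androgen-induced list was lower with GSK8814 than with GSK8815, with 3 of 28 members past the threshold, but against DMSO it passed with neither compound (medians -0.06 with GSK8814 and 0.06 with GSK8815, camera adjusted p = 0.210 and 0.0879), so the difference may lie in either. Lower output of the androgen response cannot be told apart from other causes, because the androgen-repressed list did not move clearly (adjusted p = 0.616 with an estimated correlation). UGT2B28, a steroid-metabolising gene lower by 0.71 between the compounds, is close in sequence to UGT2B11, but its change is unlikely to be read from UGT2B11 transcripts: the difference between the changes of the 2 probes was -0.597 (SE 0.141), with UGT2B11 at -0.12 between the compounds.

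In 13 of 324 groups of 4 arrays (4.01%), 1 array lay far from the other 3, and chance gives about 1 in 20. On the log2 scale these included TM7SF2 on GSK8815 replicate 3 (11.3), NUSAP1 on DMSO replicate 1 (10.9), TOP2A on GSK8815 replicate 1 (9.94), LOC652595 on GSK8815 replicate 4 (10.3), MCM2 on GSK8815 replicate 2 (9.22), TIPARP on GSK8815 replicate 3 (7.77), TYMS on DMSO replicate 4 (11.9) and GPNMB on DMSO replicate 2 (8.02). Among list means they were the androgen-induced list on GSK8815 replicate 4 (9.71), the fatty acid list on GSK8814 replicate 4 (10.7), the hypoxia list on DMSO replicate 3 (9.48) and the luminal marker list on GSK8815 replicate 3 (9.96).

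Probes without a gene name, which the comparisons above leave out, also changed. Tested probe by probe, 1280 of 5330 passed for GSK8814 against DMSO (24.0%, against 23.1% of 13189 named probes), 344 for GSK8815 against DMSO and 387 between the compounds. The largest rise of an unnamed probe with GSK8814 was 1.86 and the largest fall -1.07 on the log2 scale, and that rise exceeds the largest of the named genes tested (1.30).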

How the results depend on the processing

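The tests with cyclic loess, background subtraction and the stricter filter were chosen only after the results were seen, the others before. Of 132 named gene values, 2877 of 2903 recomputed values kept their direction and side of the threshold, 18 lost the threshold, 1 gained it and 7 changed sign. A high share was likely in advance. Several alternatives change only the test and not the log2 difference, as does leaving out an array of the third group. Most of these genes were also named for large or clear changes. Of 665 recomputed results of the 35 list results that had passed, 626 were the same and 39 lost the threshold, none with a changed direction; gains show only in the number of lists, which rose from 12, 13 and 10 to 15, 16 and 15 without a filter. Changed signs concerned only genes near 0. MYC with GSK8814 ranged from -0.0048 (without DMSO replicate 2) to 0.073 over left-out arrays. MYC with GSK8815 ranged from -0.055 to 0.034, above 0 without DMSO replicate 1 (0.017) or 3 (0.0022) or GSK8815 replicate 1 (0.034), and was 0.049 with probes averaged. MYC between the compounds was -0.028 with probes averaged, and TIPARP with GSK8815 ranged from -0.0038 (without GSK8815 replicate 3) to 0.073. The cause was not tested.

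Testing every probe, unnamed ones included, gave 4329 calls for GSK8814 against DMSO (2203 higher and 2126 lower), 1173 for GSK8815 against DMSO (576 and 597) and 1262 between the compounds (491 and 771), since more probes were tested. Requiring 1.5-fold left 153 (40 and 113), 7 (7 and 0) and 32 (5 and 27), and 0 genes fell 1.5-fold with GSK8815 at an unadjusted p under 0.05 in limma. Background subtraction gave 381 calls for GSK8815 against DMSO (213 and 168) and 156 higher between the compounds; the cause was not tested. KIF20A with GSK8815 did not pass there (adjusted p = 0.0596, in a range of 0.00401 to 0.0596). Fry passed 16 lists between the compounds, as it does not compare a list with other genes. The correlation was 0.730 without a filter, 0.740 after background subtraction (cause not tested) and 0.582 with the DMSO arrays split. The split ends the sharing of single DMSO arrays, though not of a deviation common to all of them. It also leaves fewer DMSO arrays in each comparison, so added noise may be part of the fall to 0.582.

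Leaving out each array in turn gave 2116 to 2446 calls for GSK8814 against DMSO (1095 to 1291 higher, 1017 to 1160 lower), 445 to 669 for GSK8815 against DMSO (231 to 342 higher, 214 to 329 lower) and 552 to 736 between the compounds (197 to 299, 355 to 437), with 10 to 12, 11 to 14 and 8 to 11 lists and a correlation of 0.757 to 0.792. The lowest values for GSK8815, 445 and 214, came without GSK8815 replicate 1, and NUSAP1 with GSK8815 did not pass without it (adjusted p = 0.0666, in a range of 0.00622 to 0.0666). With the replicate number as a block the counts were 2474, 650 and 691 genes and 12, 13 and 10 lists. Deviations of arrays with the same number correlated between -0.040 and 0.097, so the numbers were not taken to pair arrays.

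Not run were neqc with either offset, log2 values without background correction, median normalization, a detection p filter and a BeadChip block, because the scanner columns could not be assigned to samples or no chip is given. The deposited values were planned as an alternative and became the values analysed. Signal over background limits dim genes: the background level lies at 6.41 and the filter at 6.69 on the log2 scale.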

Other observations

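The values below were chosen after they were seen, except the list tests, which were planned.

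Metallothionein genes, which bind zinc and copper, separated by member with GSK8814. MT1H and MT1G rose by 0.35 (SE 0.0647) and 0.34 (SE 0.0672), and MT1E and MT1F by 0.30 (SE 0.0700) and 0.26 (SE 0.0584), while MT2A fell by 0.22 (SE 0.0566, limma adjusted p = 0.00373), and the list as a whole did not pass (4 of 8 higher and 1 lower, or 4 and 2 with p adjusted over the list alone, camera adjusted p = 0.169). MT2A and MT1X were lower with GSK8814 than with GSK8815, at -0.25 (adjusted p = 0.00420) and -0.29 (adjusted p = 0.000590). These genes are near-identical, so their probes can share signal.

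Of the aryl hydrocarbon receptor targets, too few of which were measured for a list test, TIPARP rose 1.76-fold and NQO1, also an NRF2 target, 1.41-fold with GSK8814, and NFE2L2 and SLC7A5 were at 0.36 and -0.15. With GSK8815 TIPARP was at 0.05 (95% interval -0.09 to 0.18), and at -0.0038 without GSK8815 replicate 3, while NQO1 and NFE2L2 were higher, by 0.26 (adjusted p = 0.00506) and 0.23 (adjusted p = 0.0174), and SLC7A5 was at -0.07. IGFBP3 and ZIC2 rose by 0.58 and 0.70 with GSK8814, whereas with GSK8815 IGFBP3 and ZIC2 were at 0.05 and 0.06. SESN1, held by the p53 and androgen-repressed lists, rose 1.42-fold with GSK8814.

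Lists of ribosomal proteins, proteasome subunits, the respiratory chain, interferon-stimulated genes, the unfolded protein response, the ATF4 response, heat shock, hypoxia, immediate early genes, TGF-beta targets, luminal markers and bromodomain proteins did not pass in any comparison. Some were measured only in part: 13 of 32 bromodomain proteins, 16 of 38 immediate early genes, 12 of 23 heat shock genes and 9 of 18 TGF-beta targets. Of the unfolded protein response 19 of 36 genes were measured, of the ribosomal proteins 51 of 52. Most genes with symbols from A to E were unnamed, so these results do not cover the unmeasured members. Of the lists that did not pass, the smallest camera adjusted p was 0.140 for GSK8814 against DMSO, 0.0544 for GSK8815 against DMSO and 0.0571 between the compounds, and the median and the test differed in sign in 3, 2 and 2 of them. The 51 measured ribosomal protein genes had a median of 0.02 with GSK8814 and 0.01 with GSK8815. ITGA6, the measured basal marker, was at -0.08 with either compound, and the immune markers FCGR3A and HLA-DRA were at 0.04 and 0.08 with GSK8814. TAGLN, a smooth muscle marker, was at 0.12, and the PXR and CAR targets GSTA1, GSTA2, POR and UGT1A3 were at 0.02, -0.03, -0.10 and 0.07.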
